A study of Homo sapiens with 6 samples.

How the data were processed

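Poly(A) RNA of 6 libraries was sequenced, 1 control and 2 knockdown libraries of each of 2 cell types, hESC and hNPC, 48 hours after siRNA transfection. The authors deposited 1 table per library with a value for each of 37773 RefSeq transcripts. The deposited values were taken as RPKM, reads per kilobase of transcript scaled to the mapped reads of the library. They are not whole numbers, and the low values of a transcript stand between libraries in ratios of small whole numbers times a constant, as whole reads divided by length and depth would. Whether reads or fragments were counted is not given in the sources used here. The submitters' processing notes name CASAVA, TopHat, TopHat2 2.0.12 and SAMtools 0.1.16, and the build hg19. The counting tool, its annotation, and whether it used strand are not given in the sources used here.

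The values were not counts, so no count model was used. The step of the low values in each library, times transcript length, gave an estimate of its mapped reads, from 37.0 to 67.6 M. At 1 RPKM a transcript of the median tested length, 2819 bases, then holds an estimated 104 to 191 reads. These depths are estimates, since the lengths come from GENCODE 29 (GRCh38) and only 54.8% to 55.8% of values under 10 reads came out within 5% of a whole read. The reference in use here is of another build than hg19, so it served for gene names, transcript lengths and shared exons, and no coordinates are given.

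Accessions were matched to symbols through a RefSeq gene table of GRCh38.p14 (36400 transcripts) and through GENCODE 29 (432 more), and 941 stayed without a symbol. Each of the 22817 genes was represented by its transcript with the highest mean over all libraries. Among genes with several transcripts, 93.7% had a lowest transcript over 0.5 times as high as the highest, as in a table that counts shared exons for every transcript. For 43 tested genes the values were identical to those of another gene. Small RNA genes (1617) were left out, because a poly(A) library measures them poorly. The 13540 genes at 1 RPKM or more in at least 1 library were tested.

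The test was limma 3.58.1 in R 4.3.3 (trend and robust) on log2(RPKM + 1), with all 6 libraries and 4 group means in 1 fit, and Benjamini-Hochberg adjustment within each comparison. This left 2 residual degrees of freedom, and the fit added a median of 3.44 from the prior. The lone control of each cell type was assumed to vary like the knockdown libraries, and both cell types to share 1 spread per gene. The limma and camera tests were two-sided, and the tests of gene families and of the hESC genes in hNPC were one-sided. Comparisons were hESC knockdown against hESC control, hNPC knockdown against hNPC control, and the difference between them. Lists of genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, over 42 tests. With an estimated correlation the set test is limited to the 2 residual degrees of freedom, so it has little power here. Of 22 lists 21 had at least 5 tested members. The lists were SOX family, pluripotency, trophectoderm and extraembryonic, mesendoderm, neural progenitor, neuronal differentiation, glial, neural crest, mesenchymal and fibroblast, epidermal and non-neural ectoderm, Notch pathway, WNT targets, sonic hedgehog pathway, BMP and TGF-beta targets, FGF and ERK targets, p53 targets, cell cycle and mitosis, interferon response, unfolded protein and integrated stress response, HOX genes, cholesterol synthesis and siRNA machinery. Some genes sit in several lists, such as EOMES, MSX2 and HES5. The targets SOX2 and SOX3 are members of the SOX family and neural progenitor lists. Control libraries were compared without a test, by the percentile of a list's median among 10000 random lists of the same size matched on mean expression in 20 bins.

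The genes named in the text follow a rule fixed before the data were examined, as were the comparisons, the lists and the alternatives named first below. The rule takes SOX1, SOX2 and SOX3. It takes the 10 largest rises and 10 largest falls past the threshold with both knockdown libraries on the same side. Where fewer pass, these are filled up with the genes whose smaller fold change of both libraries is largest. Also taken are the 5 largest differences between cell types among genes past the threshold, and up to 4 members of each list with the smallest p. POU5F1 and the list members named beyond these 4, such as NANOG, AXIN2 and TBXT, were chosen after their values were seen. The rule picks more list members than the text names, and 1 item is not reported here.

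The fit was tested on simulated data with 200 changed genes among 13540 and 20 simulations per comparison. With gene variances drawn from the fitted prior, it recovered 2.4% of changes of 1 log2 unit and 72.0% of changes of 2 log2 units in hESC, with 3.85 false calls among 78.2 on average. With the already shrunken gene variances in their place, an earlier form of the simulation, it recovered 56.0% and 97.6% with 17.6 false calls among 171.2. In hNPC the first form recovered 2.5% and 72.6%, with 4 false calls among 79.0. Recovery was thus nearly equal in the cell types. The knockdown pairs in the data differ in spread (SD of the log2 difference 0.458 in hESC and 0.27 in hNPC). The simulations do not carry this difference, so they do not give the false calls or the recovery of either comparison in the data.

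Alternatives fixed beforehand were quantile normalization, no filter, a mean of at least 5 RPKM, pseudocounts of 0.1 and 0.5, no trend and no robust step, each cell type alone, a replicate block by siRNA number, each knockdown library left out in turn, and other thresholds. Median scaling, small RNA genes kept, the mean over transcripts, the protocadherin gamma cluster as 1 gene, the number of genes over 1 log2 unit from the control and the set tests of the difference between cell types were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.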

Results

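Messenger RNA was sequenced from 6 libraries of human cells to ask which genes depend on SOX2, a transcription factor of the SOXB1 family that is active in pluripotent and in neural precursor cells. Human embryonic stem cells (hESC) of the line H9 and neural progenitor cells (hNPC) derived from them were collected 48 hours after siRNA transfection. In hESC, 2 siRNA sets were directed against both SOX2 and SOX3. In hNPC, 2 siRNAs were directed against SOX2 alone. Each cell type had 1 control library, transfected with a non-targeting siRNA, and 2 knockdown libraries, here named KD1 and KD2. The estimated depth was 60.5 M mapped reads in the hESC control, 67.6 and 48.1 M in hESC KD1 and KD2, 55.5 M in the hNPC control, and 37.0 and 48.4 M in hNPC KD1 and KD2. Values are given in RPKM, and fold changes are on the scale of log2(RPKM + 1), which understates the change of weakly expressed genes. The knockdown libraries of a cell type differ in siRNA, and no source used here says whether they came from separate cultures. The limma p-values therefore measure only the spread within the 2 knockdown pairs, which may be technical. The set tests at the preset correlation instead compare a list with the other genes. A shift of the lone control across a list would therefore count as a change. The fit pools both pairs, though the SD of the log2 difference was 0.458 in hESC and 0.27 in hNPC. The hESC limma p-values thus borrow from the closer hNPC pair, and the hNPC limma p-values from the wider hESC pair.

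The targeted genes were examined first, since they check the labels. SOX2 stood at 71.4 RPKM in the hESC control, 42.3 in hESC KD1 and 97.1 in the hESC library labelled KD2, so the library labelled KD2 held more SOX2 mRNA than its control. The ratio to the control was 0.593 in KD1 and 1.36 in the library labelled KD2, and the fold change over both was -0.15 log2 (SE 0.47; adjusted p = 0.893, limma). The direction of that fold change turned with quantile normalization, which gave 0.015, and without KD1, which gave 0.44. SOX3, the other target in hESC, stood at 3.44 RPKM in the control and 1.25 ± 0.224 (SD, n = 2) after knockdown, with 1.40 in KD1 and 1.09 in the library labelled KD2 (-0.99 log2, SE 0.21; adjusted p = 0.108, limma). In hNPC, SOX2 stood at 106.0 RPKM in the control, 68.3 in KD1 and 59.2 in KD2 (-0.73 log2, SE 0.47, adjusted p = 1, limma). This SE is pooled with the hESC pair, which stood at 42.3 and 97.1 RPKM. The hNPC libraries themselves lay close, at -0.63 log2 in KD1 and -0.83 in KD2. SOX1, the third SOXB1 gene and not a target, stood at 0.598 RPKM in control hESC against 26.9 in control hNPC, and at 26.3 ± 2.12 (SD, n = 2) in the hNPC knockdown libraries. None of the 3 SOXB1 genes passed the test in either cell type.

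**Figure D1:**
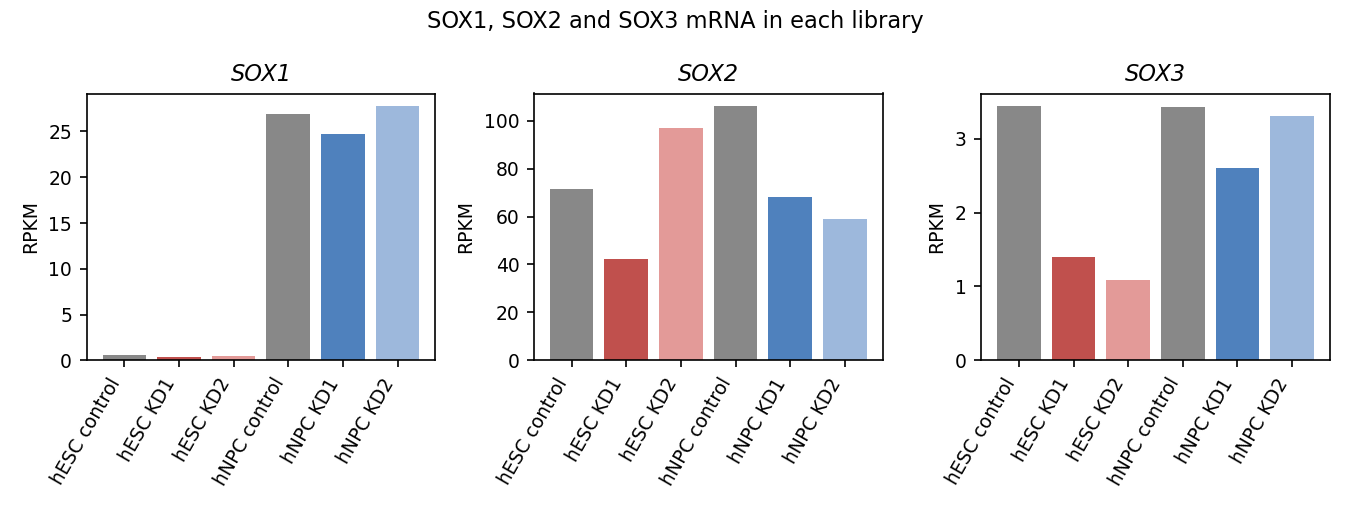
SOX1, SOX2 and SOX3 mRNA in RPKM (vertical axes, starting at 0) in each of the 6 libraries, 1 bar per library. SOX2 in the hESC library labelled KD2, at 97.1 RPKM, lies above the hESC control at 71.4, while SOX3 lies below the control in both hESC knockdown libraries.

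The first comparison asked which genes changed in hESC when SOX2 and SOX3 were targeted. Of the genes in lists fixed beforehand, 7 of 19 WNT targets and 4 of 15 mesendoderm genes rose with 1 WNT target falling, and 7 of 28 pluripotency genes fell with 1 rising. SP5, a transcription factor induced by WNT signalling, rose from 0.051 RPKM to 51.8 ± 8.71 (SD, n = 2), and WLS, the carrier that WNT proteins need for secretion, rose from 0.89 to 79.4 ± 22.7. EOMES, a T-box factor of the primitive streak, rose from 0.079 to 24.1 ± 14.8, and NANOG, a core pluripotency factor, fell from 33.1 to 11.2 ± 1.95. These directions rest in part on the library labelled KD2, in which SOX2 mRNA lay above the control. Of 13540 genes tested, 218 passed an adjusted p of 0.05 (limma), 144 higher and 74 lower, and each of the 218 lay on the same side of the control in both knockdown libraries. Both libraries on one side would be met by 66.7% of unselected genes by chance alone. A call requires a shift that is large against the spread between libraries, which nearly forces both onto 1 side. The count is therefore no separate support for agreement between the siRNA sets. At an unadjusted p below 0.05 there were 2395 genes, against 677 expected by chance.

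The other genes with the largest rises included secreted regulators of signalling. The WNT-binding protein FRZB rose from 1.18 RPKM to 59.7 ± 12.5 (SD, n = 2), the decoy receptor TNFRSF11B from 0.233 to 32.5 ± 17.5, and the activin-binding protein FST from 3.76 to 93.1 ± 49.5. The guidance ligand SLIT2 rose from 1.02 to 41.6 ± 5.18. The WNT pathway regulator DACT1 rose from 2.04 to 64.0 ± 9.65, the homeobox gene MSX1 from 0.069 to 16.5 ± 2.88, and the apelin receptor gene APLNR from 0.158 to 17.4 ± 3.08. The fold changes of the 10 largest rises ran from 3.98 to 5.64 log2, with adjusted p between 0.00619 and 0.0291 (limma). Among the largest falls, the tyrosine kinase gene LCK fell from 15.6 RPKM to 1.08 ± 0.672, TRIML2 from 14.7 to 0.923 ± 0.101 and the chemokine gene CXCL5 from 15.9 to 1.34 ± 0.259. ZDHHC22 fell from 13.4 to 1.02 ± 0.374, the adenylate kinase gene AK4 from 33.9 to 4.13 ± 1.31, and POLR3G, a subunit of RNA polymerase III, from 68.0 to 10.3 ± 0.096. GPR160, PLAAT3 and RND3 fell by 2.59, 2.36 and 2.28 on the log2 scale. THY1, a surface protein of stem cells and fibroblasts, fell from 114 RPKM to 23.1 ± 1.77. The 10 largest falls ran from -3.03 to -2.26 log2, with adjusted p between 0.0134 and 0.0465 (limma).

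**Figure D2:**
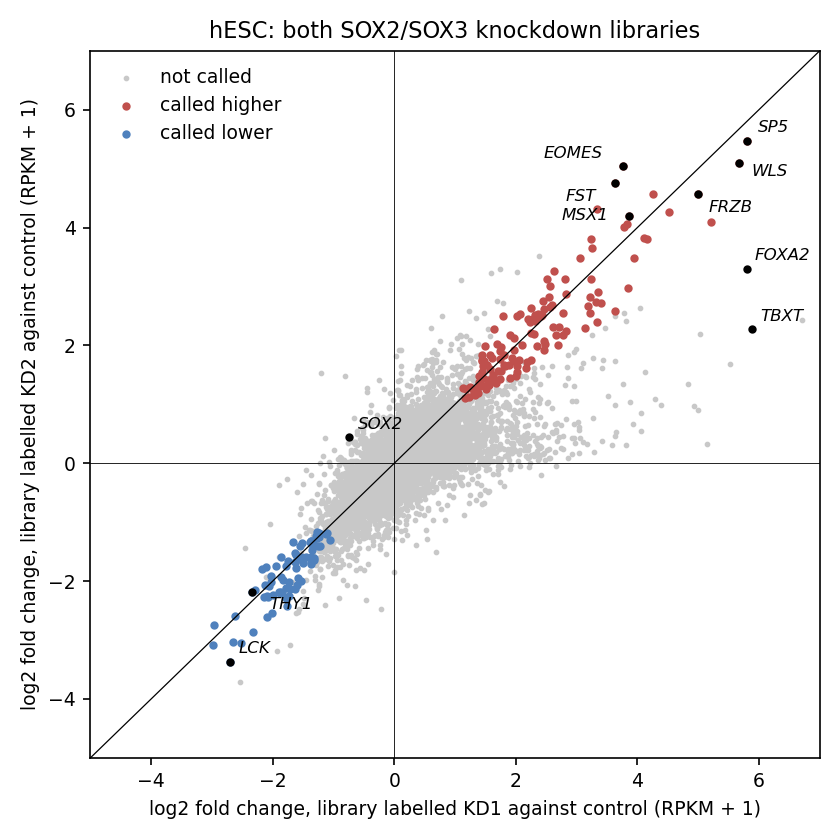
Fold change against the hESC control in KD1 (horizontal axis, log2 of RPKM + 1) and in the library labelled KD2 (vertical axis, same unit), 1 point per gene, with equal values along the diagonal, genes past an adjusted p of 0.05 in red (144 higher) or blue (74 lower), and named genes in black. Called genes lie on the same side of 0 in both libraries, SOX2 lies at -0.74 in KD1 and 0.44 in the library labelled KD2, and TBXT and FOXA2 lie far to the right of the diagonal.

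Gene lists fixed before the data were examined were then tested as sets in hESC (camera, preset correlation of 0.01, 42 tests), and 8 of 21 passed. The library labelled KD2, with SOX2 above the control, again enters each direction. Among the 8 lists the estimated correlation ran from -0.056 (mesenchymal) to 0.491 (cell cycle), with -0.009 for pluripotency. For the pluripotency and mesenchymal lists, below the preset, correlation does not account for the higher p with the estimate. The pluripotency list was lower (median -1.09 log2, 28 genes; adjusted p = 4e-12, and adjusted p = 0.299 with an estimated correlation). Of its members, 7 fell, 1 rose and 20 did not pass, while 19 were lower and 1 higher when adjusted over the list alone, and 21 lay below the control in both libraries. The members that fell included USP44 (61.1 to 12.8 ± 1.16 RPKM), PRDM14 (13.0 to 2.29 ± 0.1), L1TD1 (221 to 69.8 ± 1.77) and TERF1 (137 to 35.8 ± 7.41). POU5F1, named after its value was seen, stood at 87.3 RPKM in the control and 48.2 ± 1.45 after knockdown (adjusted p = 0.0892, limma).

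The mesendoderm list, genes of the primitive streak and its derivatives, was higher in hESC (median 1.31 log2, 15 genes; adjusted p = 2.64e-05, and adjusted p = 0.752 with an estimated correlation). EOMES, MIXL1, WNT3 and EVX1 rose and 11 members did not pass, while 7 were higher when adjusted over the list alone. MIXL1 rose from 0.166 to 7.01 ± 3.23 RPKM (SD, n = 2), WNT3 from 0.333 to 3.88 ± 0.514, and EVX1, listed at 0 in the control, stood at 2.27 in KD1 and 1.97 in the library labelled KD2. The list of WNT targets was higher (median 0.96 log2, 19 genes; adjusted p = 0.000324, and adjusted p = 0.79 with an estimated correlation). SP5, APCDD1, LEF1, SP8, DKK1, NKD1 and AXIN2 rose, SFRP2 fell, and 11 did not pass, while 9 were higher and 1 lower when adjusted over the list alone. The median of the WNT targets was 1.49 log2 in KD1 and 0.42 in the library labelled KD2. APCDD1 rose from 1.81 to 36.2 ± 8.37 RPKM and NKD1 from 0.567 to 5.50 ± 0.292, both inhibitors of WNT signalling. SFRP2, a secreted WNT modulator, fell from 151 to 34.2 ± 4.14.

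The sonic hedgehog list was higher in hESC (median 0.52 log2, 12 genes; adjusted p = 0.00189, and adjusted p = 0.752 with an estimated correlation). Its members BOC and GAS1, both co-receptors of hedgehog proteins, rose, BOC from 0.891 to 4.56 ± 0.551 RPKM (SD, n = 2), and 3 members were higher when adjusted over the list alone. The mesenchymal list was higher (median 0.63 log2, 15 genes; adjusted p = 0.00233, and adjusted p = 0.752 with an estimated correlation). COL1A2, a collagen chain, rose from 11.9 to 101 ± 15.7 RPKM, PDGFRB rose by 1.27 log2, and THY1 fell, while 7 were higher and 1 lower when adjusted over the list alone. The neural progenitor list was higher (median 0.38 log2, 26 genes; adjusted p = 0.0166, and adjusted p = 0.79 with an estimated correlation), with CDH2, the neural cadherin, rising from 10.1 to 32.6 ± 4.88 RPKM and 25 members not passing. The count adjusted over the list alone was 5 higher and 1 lower. The neural crest list was higher (median 0.75 log2, 15 genes; adjusted p = 0.0418, and adjusted p = 0.79 with an estimated correlation). Its median was 0.21 log2 in KD1 and 1.42 in the library labelled KD2, whose SOX2 lay above the control. In this list MSX1 and MSX2 rose, and 7 were higher and 2 lower when adjusted over the list alone. The cell cycle list was lower (median -0.20 log2, 34 genes; adjusted p = 0.00122, and adjusted p = 0.814 with an estimated correlation) with 0 members called, over all genes or adjusted over the list alone, and 23 below the control in both libraries. Without the library labelled KD2 the adjusted p was 0.145 for neural crest and 0.176 for the neural progenitor list. It was 0.107 for the cell cycle with quantile normalization and 0.0558 for the neural progenitor list with no filter on low values.

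The other 13 lists tested did not pass in hESC. Single members of some rose: MSX1, GREM1, ID3 and MSX2 of the BMP and TGF-beta list (adjusted p = 0.264 as a set; 6 higher and 3 lower adjusted over the list alone), GAD1, STMN2 and EOMES of the neuronal list (adjusted p = 0.123; 5 higher and 2 lower adjusted over the list alone), BTG2 of the p53 list (adjusted p = 0.245; 1 higher adjusted over the list alone), and EOMES and MSX2 of the trophectoderm list (adjusted p = 0.261; 2 higher and 1 lower adjusted over the list alone). GAD1, which makes the transmitter GABA, rose from 0.081 to 15.2 ± 1.83 RPKM (SD, n = 2). With 0 members called over all genes, the adjusted p of the set was 0.0779 for the unfolded protein and integrated stress response, 0.524 for cholesterol synthesis, 0.544 for the interferon response, 0.616 for the siRNA machinery and for the SOX family, 0.658 for FGF and ERK targets, 0.846 for the epidermal list, 0.881 for the Notch pathway and 0.91 for the glial list. Adjusted over the list alone, 3 SOX genes were higher and 3 lower, with the target SOX3 among the lower. In the same way, 3 FGF and ERK targets were higher and 4 lower, and 2 Notch genes were higher and 3 lower. Of the interferon genes 1 was higher, and none passed in the other 5 of these lists. The set direction differed in sign from the median for cholesterol synthesis, the interferon response, the siRNA machinery, FGF and ERK targets, the epidermal list and the Notch pathway, and from the mean for the interferon response, the SOX family and the Notch pathway. Of the HOX list 2 genes were tested, too few for a set test, and HOXB2 and HOXA2 had adjusted p of 0.653 and 0.956 (limma).

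Protocadherin gamma genes, which share their last exons, made up 22 of the 144 genes called higher in hESC, and reads of the shared exons cannot be split between them. With the cluster entered as 1 gene, an alternative chosen after seeing the data, 143 genes passed, 89 higher and 54 lower. The lower calls, none of them in the cluster, had been 74. Genes outside the cluster thus lost their calls as well, since the adjustment depends on all genes tested. The counts of called list members given above come from the fit with every cluster gene. The call count rested on single libraries: it was 859 (399 higher, 460 lower) without KD1, 1379 (990 higher, 389 lower) without the library labelled KD2, and 0 without either hNPC knockdown library. It was also 0 with hESC fitted alone and 57 (16 higher, 41 lower) with no filter on low values. Libraries scaled to equal medians gave 112 genes higher and 106 lower, and quantile normalization 131 and 122. The median fold change of all genes was 0.07 log2 as deposited and -0.07 with median scaling.

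The second comparison asked which genes changed in hNPC when SOX2 was targeted. No gene passed an adjusted p of 0.05 (limma), 406 had an unadjusted p below 0.05 where chance gives 677, and the lowest adjusted p was 0.388, for PPP1R1A. The number at an unadjusted p below 0.05 was 685 without either hESC knockdown library and 681 with hNPC fitted alone. The values that follow are therefore descriptions. PPP1R1A, an inhibitor of protein phosphatase 1, stood at 18.3 RPKM in the control and 3.02 ± 0.151 (SD, n = 2) after knockdown. FABP7, a fatty acid binding protein of radial glia, stood at 34.9 against 8.31 ± 0.973. The smooth muscle actin gene ACTG2 stood at 7.64 against 1.55 ± 0.056, IGFBP3 at 19.2 against 5.38 ± 0.721 and SMOC1 at 8.83 against 1.97 ± 0.656. The peptide genes ADM and SCG2 stood at 26.0 against 7.19 ± 1.67 and at 8.28 against 2.40 ± 0.275. DTX4, PDGFB and EMP1 had fold changes of -1.60, -1.58 and -1.49 log2.

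On the other side of the hNPC control, LAMC1, a laminin chain, stood at 24.6 RPKM in the control and 89.4 ± 20.7 (SD, n = 2) after knockdown. FRZB stood at 2.23 against 11.6 ± 0.126, and APCDD1 at 19.9 against 52.4 ± 2.39. POU3F1, a POU factor of neural precursors, stood at 11.1 against 32.3 ± 2.90, NQO1, a quinone reductase, at 24.1 against 60.9 ± 11.2, and SLITRK1, which like FRZB and APCDD1 rose in hESC, at 2.52 against 10.3 ± 1.92. ATP8A1, GDF10, GFRA1 and IER5L had fold changes of 1.46, 1.29, 1.20 and 1.15 log2. In simulations of this design, with gene variances drawn from the fitted prior, 2.5% of changes of 1 log2 unit and 72.6% of changes of 2 log2 units were recovered in hNPC. With already shrunken gene variances, a simulation that made more false calls, 59.4% and 97.8% were recovered. The simulations gave nearly the same recovery in hESC, so they do not carry the closer spread of the hNPC pair. Recovery in the hNPC data may therefore differ. Most fold changes named here lie below 2 log2 units.

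**Figure D3:**
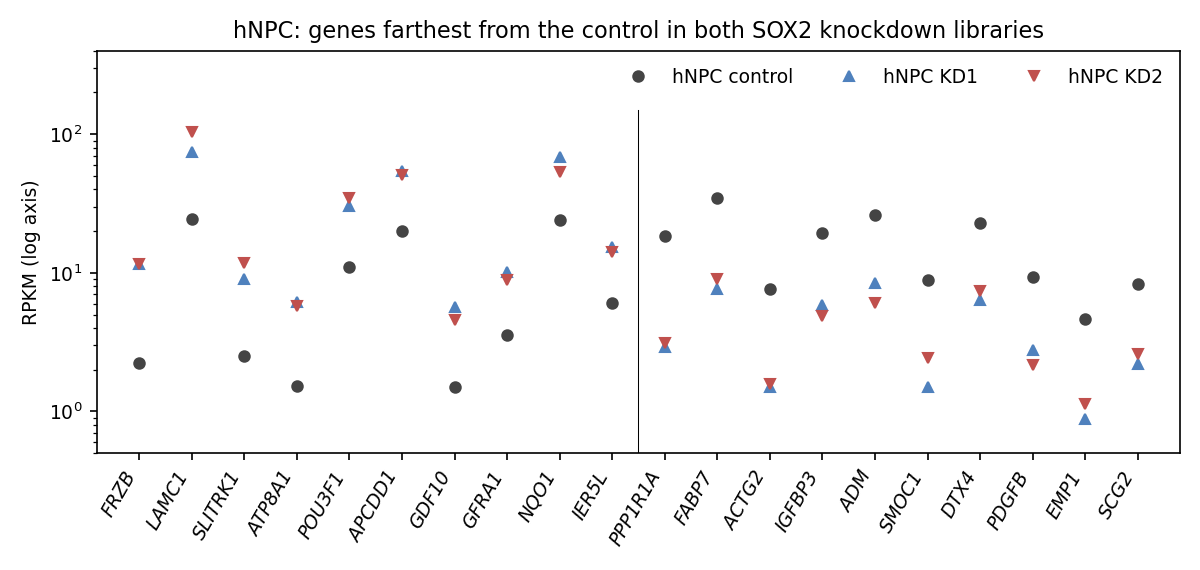
RPKM (log axis) of the 20 hNPC genes with both SOX2 knockdown libraries farthest above the control (left of the line) or below it (right of the line), with circles for the control, upward triangles for KD1 and downward triangles for KD2. PPP1R1A stands at 18.3 RPKM in the control and at 2.91 and 3.12 in the knockdown libraries, and no gene shown passed the test.

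Tested as sets, 7 of 21 lists passed in hNPC, with no single member called over all genes. The cholesterol synthesis list was lower (median -0.33 log2, 24 genes; adjusted p = 2.85e-12, and adjusted p = 0.299 with an estimated correlation). Of its 24 members 21 lay below the control in both libraries, and adjusted over the list alone 0 passed. The estimated correlation of this list, -0.042, lay below the preset of 0.01. For the other lists that passed in hNPC it lay above the preset, from 0.116 (neural crest) to 0.491 (cell cycle) and 0.455 (p53). Their adjusted p at the preset assumes less correlation than was estimated. DHCR7, the last enzyme of the pathway, had a fold change of -0.61 log2 (SE 0.15), and LSS, which makes lanosterol, stood at 27.4 RPKM in the control against 16.6 ± 0.428 (SD, n = 2). The Notch list was lower (median -0.34 log2, 18 genes; adjusted p = 3.34e-05, and adjusted p = 0.752 with an estimated correlation), with 3 members lower adjusted over the list alone. Its leading members DTX4, HES4 and HES5 had fold changes of -1.60, -0.85 and -1.34 log2, and HES5, a Notch effector, stood at 2.14 RPKM in the control against 0.041 in KD1 and 0.477 in KD2. The unfolded protein and integrated stress response list was lower (median -0.26 log2, 19 genes; adjusted p = 0.0063, and adjusted p = 0.79 with an estimated correlation), with 12 members below the control in both libraries, 0 adjusted over the list alone, and XBP1 at 37.9 against 24.6 ± 4.65 RPKM.

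The list of WNT targets was higher in hNPC (median 0.12 log2, 19 genes; adjusted p = 0.00347, and adjusted p = 0.79 with an estimated correlation). Adjusted over the list alone, 2 were higher and 1 lower. LEF1 stood at 2.30 RPKM in the control and 6.04 ± 1.16 (SD, n = 2) after knockdown, NKD1 at 2.40 against 5.61 ± 0.648, and SFRP2 at 32.5 against 12.5 ± 0.674. The p53 list was higher (median 0.22 log2, 20 genes; adjusted p = 0.00415, and adjusted p = 0.814 with an estimated correlation), with CDKN1A, an inhibitor of the cell cycle, at 29.5 against 63.2 ± 8.13 RPKM and 0 members adjusted over the list alone. The cell cycle list was also higher (median 0.12 log2, 34 genes; adjusted p = 0.0166, and adjusted p = 0.838 with an estimated correlation), with PLK1 at 17.3 against 23.4 ± 4.09 RPKM. The neural crest list was higher (median 0.11 log2, 15 genes; adjusted p = 0.0242, and adjusted p = 0.79 with an estimated correlation), with SNAI2 at 7.47 against 14.8 ± 4.36 RPKM. For both of these lists 0 members passed adjusted over the list alone. Between the hNPC knockdown libraries the cell cycle median differed by 0.25 log2, more than its change of 0.12 against the control. That of the unfolded protein and integrated stress response list differed by 0.27, beside a change of -0.26. Without KD1, 4 lists passed in hNPC, with WNT targets the 1 higher list left and the same 3 lists lower. The adjusted p was then 0.168 for p53 targets, 0.917 for the cell cycle and 0.0641 for neural crest. Without KD2 it was 0.249 for the unfolded protein and integrated stress response, and with no filter on low values 0.299 for WNT targets and 0.361 for neural crest.

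**Figure D4:**
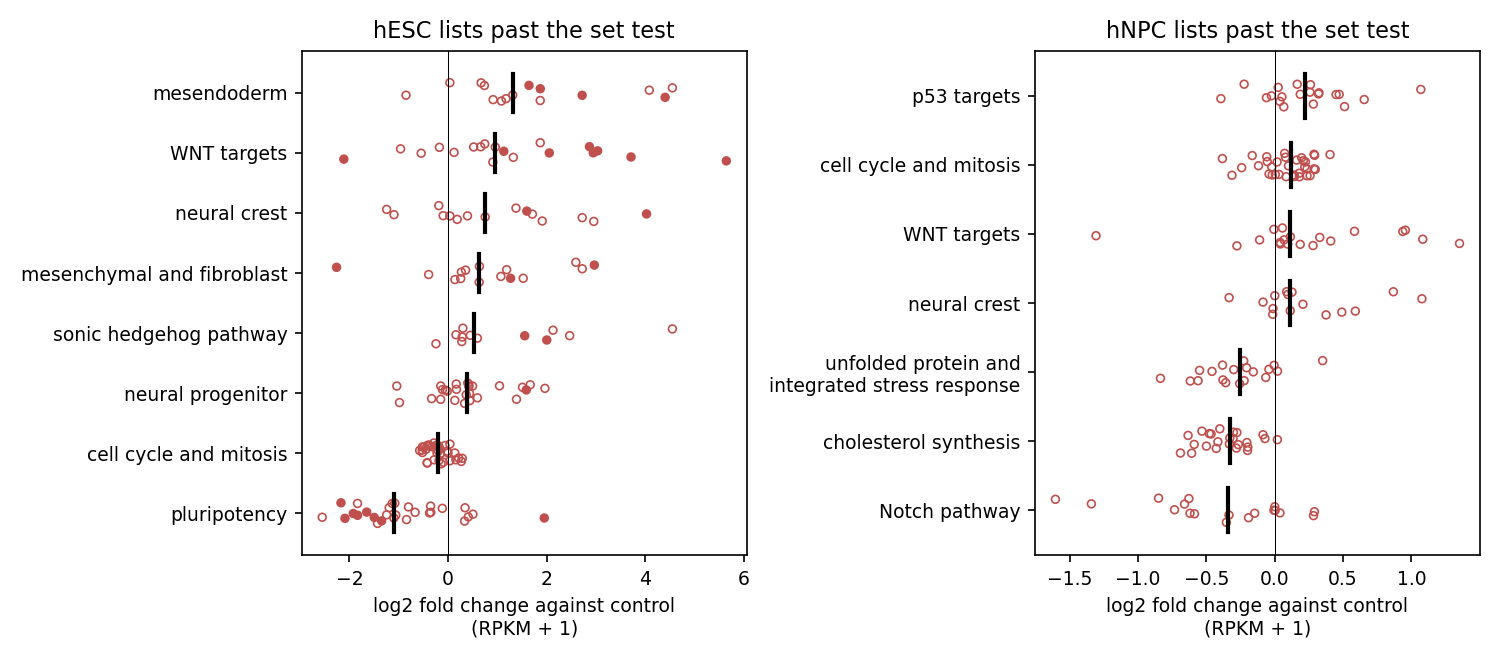
Fold change against the control (horizontal axes, log2 of RPKM + 1) of the tested members of each list that passed the set test in hESC (left, 8 lists) and in hNPC (right, 7 lists), 1 circle per gene, filled where the gene passed an adjusted p of 0.05 over all genes, with a bar at the list median. The pluripotency median lies at -1.09 in hESC and the Notch median at -0.34 in hNPC, and the axes of the panels have different ranges.

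The other 14 lists did not pass in hNPC. The neural progenitor list had an adjusted p of 0.0779 (camera, median -0.10 log2, 26 genes), with 3 members lower adjusted over the list alone. Its median was -0.133 log2 in KD1 and 0.004 in KD2. Its leading members PLAGL1, FABP7 and HES5 had fold changes of -1.17, -1.95 and -1.34 log2, and the neural stem cell filament NES had a fold change of -0.55 log2 (SE 0.15). The SOX family had an adjusted p of 0.261, with 1 member lower adjusted over the list alone. That member, SOX21, known to oppose SOXB1 factors, stood at 33.3 RPKM in the control against 10.5 ± 2.75. The adjusted p was 0.13 for neuronal differentiation, 0.261 for the trophectoderm list, 0.371 for BMP and TGF-beta targets, 0.687 for mesendoderm, and 0.846 for pluripotency, the interferon response and the glial list. It was 0.881 for FGF and ERK targets, the mesenchymal list, the epidermal list, the siRNA machinery and the sonic hedgehog list. Adjusted over the list alone, 1 trophectoderm gene was lower, 1 mesenchymal gene was lower, and 1 glial gene was higher and 1 lower, with none in the other lists named in this paragraph. The sign of the set direction differed from that of the median for the trophectoderm, mesendoderm, FGF and ERK, siRNA machinery and sonic hedgehog lists, and from that of the mean for the mesenchymal list and the siRNA machinery. The tested HOX genes HOXA2 and HOXB2 had adjusted p of 1 (limma).

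The third comparison tested whether the response differed between the cell types, with the hESC change subtracted from the hNPC change. SP5, WLS, OLFM3, DACT1 and SAMD3 responded less in hNPC than in hESC, where the library labelled KD2, with SOX2 above the control, is part of the response. SP5 differed by -5.65 log2 (SE 0.33) and WLS by -5.49 (SE 0.39). WLS stood at 51.7 RPKM in control hNPC and 48.0 ± 5.67 (SD, n = 2) after knockdown, while SP5 stood at 0.176 against 0.175 ± 0.127. OLFM3, DACT1 and SAMD3 differed by -4.43, -4.39 and -3.95 log2. Of 13540 genes 6 passed (adjusted p = 0.0475 for each, limma), the remaining one being GAD1, and all 6 were lower in this direction, with 1201 genes at an unadjusted p below 0.05. No gene was called in both cell types, since none was called in hNPC. Cell type and siRNA target, SOX2 with SOX3 or SOX2 alone, differ together in this design. The number of genes was 287 (166 higher, 121 lower) without hESC KD1, 742 (163 higher, 579 lower) without the hESC library labelled KD2, 0 without either hNPC knockdown library, and 71 among genes of at least 5 RPKM on average. It was 0 with median scaling, with no filter on low values and without the trend and robust steps, where 1379, 1815 and 1229 genes had an unadjusted p below 0.05 (limma).

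Measured by size alone, 332 genes lay over 1 log2 unit above the control in both hESC knockdown libraries and 192 below it, but 280 above and 314 below with quantile normalization, and 254 and 291 with median scaling. In hNPC the numbers were 11 and 29. The libraries labelled KD1 and KD2 differed by over 1 log2 unit for 606 genes in hESC and 71 in hNPC. With 1 library alone, hESC had 1214 such genes in KD1 and 890 in the library labelled KD2, and hNPC had 113 in KD1 and 103 in KD2.

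The controls were compared with each other to describe the starting states, with 1 library of each and no test run. Against hESC, the hNPC control held more of the neural progenitor list, with a median of 2.08 log2 over 26 genes and 20 members over 1 log2 unit higher. The neuronal list had a median of 1.18 log2, the sonic hedgehog list 1.29, the p53 list 0.73, the unfolded protein and integrated stress response list 0.66, the FGF and ERK list 0.46 and the Notch list 0.38. The pluripotency list had a median of -3.37 log2 in the same direction, with 25 of 28 members over 1 log2 unit lower in hNPC. The epidermal list had a median of -4.61 over 7 genes and the BMP and TGF-beta list -0.51. The 7 were TFAP2C, GRHL2, EPCAM, CLDN4, KRT8, KRT18 and KRT19, while KRT5, KRT14 and TP63 were too low to test. These 10 medians lay outside the central 95% of 10000 random lists matched on size and mean expression, and those of the other 11 lists lay inside. Among these 11, the medians were -0.27 for the siRNA machinery, -0.22 for trophectoderm, -0.07 for mesendoderm, -0.05 for the cell cycle, 0.16 for WNT targets, 0.18 for the SOX family, 0.12 for cholesterol synthesis, 0.27 for the interferon response, 0.33 for neural crest and for the mesenchymal list, and 0.28 for the glial list.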

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

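All tests of explanations in this part, and the set tests of the difference between cell types, were chosen after the results were seen.

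A test of the difference between cell types singled out 6 genes, all with a smaller response in hNPC than in hESC, and in hESC all lay above the control in both knockdown libraries. The difference was -5.65 log2 for SP5, -5.49 for WLS, -4.43 for OLFM3, -4.39 for DACT1, -3.95 for SAMD3 and -3.88 for GAD1. The change against the control was tested by list with the same contrast (camera, preset correlation). This change was higher in hNPC than in hESC for pluripotency (adjusted p = 1.2e-13) and for the cell cycle (adjusted p = 8.88e-06). It was lower in hNPC for mesendoderm (adjusted p = 4e-07), the neural progenitor list (adjusted p = 0.000898), the sonic hedgehog list (adjusted p = 0.00217), WNT targets (adjusted p = 0.00233), cholesterol synthesis (adjusted p = 0.00595), the mesenchymal list (adjusted p = 0.00672), neuronal differentiation (adjusted p = 0.00684) and the trophectoderm list (adjusted p = 0.024). None of the 10 passed with an estimated correlation, where the lowest adjusted p was 0.265 (camera on 2 residual degrees of freedom). In the controls, 25 of 28 pluripotency members were over 1 log2 unit lower in hNPC than in hESC. They had little room to fall in hNPC, so the fall in hESC nearly fixed the sign of this difference. Of the 941 transcripts without a symbol, which no comparison used, 9 lay over 1 log2 unit above the control in both hESC knockdown libraries and 0 in both hNPC knockdown libraries.

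SOX2 mRNA in the hESC library labelled KD2 lay above the control. A swap of that library with the control is argued against by distance: 1214 genes differed by over 1 log2 unit between KD1 and the control, but 606 between KD1 and the library labelled KD2. Scaling does not remove the pattern, since the log2 ratio of SOX2 to the control in that library was 0.44 as deposited and 0.305 and 0.597 under median scaling and quantile normalization. A wrong label with a partner outside these libraries, and an siRNA set that acted on SOX3 (ratio 0.316) but not on SOX2 mRNA, stay open, and no biological explanation was tested.

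The 22 protocadherin gamma genes called higher in hESC share their last exons. Each has a short transcript without these exons, and its RPKM was over 2 times that of the control in both libraries for 6 of the 22, PCDHGA9, PCDHGB6, PCDHGB7, PCDHGC3, PCDHGC4 and PCDHGC5. PCDHGC4's short form stood at 0.374 RPKM in the control and at 9.96 and 8.77 in the knockdown libraries, and PCDHGA1's at 0.302 against 0.283 and 0.262. Reads of the shared exons counted for every member may therefore account for the calls of most of the cluster, and a higher level of these 6 stays open as the source of those reads.

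In hESC 524 genes lay over 1 log2 unit from the control in both knockdown libraries, and in hNPC 40. Among well-expressed genes the numbers were 292 and 23 (ratio 12.7). That count could hardly point to lower depth in hNPC, since fewer reads tend to widen fold changes. The libraries labelled KD2 had near equal estimated depth, 48.1 M in hESC and 48.4 M in hNPC. They had 890 and 103 genes over 1 log2 unit from the control, which argues against lower depth for these libraries. Scaling is argued against by the ratio under quantile normalization and median scaling, 12.7 or more against 13.1 as deposited. For a stronger loss of SOX2 mRNA in hESC, the SOX2 fold change, hNPC minus hESC, was -0.58 log2 (SE 0.67). That sign is of a weaker loss in hESC, within an error that includes the split of the hESC libraries. The ratio to the control was 0.593 in KD1 and 1.36 in the library labelled KD2, against 0.644 and 0.558 in hNPC. By this ratio neither hESC library lay below both hNPC libraries. In RPKM, hESC KD1 held less SOX2 mRNA than either hNPC knockdown library. Yet 1214 genes in KD1 and 890 in the library labelled KD2 lay over 1 log2 unit from the control. In hNPC the numbers were 113 in KD1 and 103 in KD2. For the library labelled KD2, if its label is right, these values argue against a stronger loss of SOX2 mRNA as the source of the excess. For KD1 they cannot decide, since its ratio lay between those of hNPC and its RPKM lay below them. The cell type and the added targeting of SOX3 in hESC differ together, and both stay open, untested.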

How the results depend on the processing

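The call counts rest on 2 residual degrees of freedom. At 1 RPKM a transcript of the median length of 2819 bases holds an estimated 104 to 191 reads, and shorter transcripts hold fewer. Median scaling, small RNA genes kept and the protocadherin gamma cluster as 1 gene were alternatives chosen after seeing the data. The 218 genes called in hESC became 57 with no filter, 0 with each cell type fitted alone, 143 with the protocadherin cluster as 1 gene, 492 at an adjusted p below 0.1, and 0 to 1379 when 1 knockdown library was left out. The 6 genes of the difference became 3 with quantile normalization, 0 with no filter, 71 at a mean of at least 5 RPKM, 28 with a pseudocount of 0.1, 0 without trend and robust steps, 0 with median scaling, 0 with small RNA genes kept, 14 at an adjusted p below 0.1, and 0 to 742 with 1 library left out. By construction, a fit without an hESC knockdown library takes its spread from the hNPC pair alone (SD of the log2 difference 0.27), and a fit without an hNPC library, or of hESC alone, from the hESC pair (0.458), each with 1 residual degree of freedom. For the other settings the cause was not tested. The hNPC count was 0 under each alternative (270 to 685 genes at an unadjusted p below 0.05), and so was the overlap. Lists called were 7 in hESC with quantile normalization and 5 in hNPC with no filter, 8 to 11 in hESC and 4 to 9 in hNPC with 1 library left out, and 0 and 0 with an estimated correlation. The set test with an estimated correlation uses the 2 residual degrees of freedom, so its 0 calls do not show that correlation removed them. SOX2 in hESC was 0.015 log2 with quantile normalization and -0.74 to 0.44 with 1 library left out.

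Genes over 1 log2 unit from the control in both libraries numbered 524 in hESC, 292 at a mean of at least 5 RPKM (fewer genes tested), 1137 with a pseudocount of 0.1, and 890 to 1214 with 1 library. In hNPC the 40 became 23, 128, 64 with a pseudocount of 0.5, and 103 to 113 with 1 library. Of the control comparison 10 list medians lay outside the random range, and 16 with the knockdown libraries in place of the controls. The replicate block by siRNA number gave 244 genes in hESC, 0 in hNPC and 8 for the difference. Same-numbered libraries deviated together with a correlation of 0.038 across genes, which gives no sign of pairing but cannot exclude a shared siRNA or batch. Apart from the SOX2 and SOX3 fold changes and the counts above, single genes, lists and list medians kept direction and side of the threshold in 1076 alternatives, lost the threshold in 237, and moved without a test in 34. None of these reversed.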

Other observations

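The tests in this part were chosen after the data were seen. Among 456 gene families defined by a shared symbol stem, 3 were over-represented among the genes called higher in hESC (Fisher's exact test across genes, one-sided, which treats genes as independent). Of these, 2 are the protocadherin gamma stems that share reads. The third was the Iroquois family of homeobox genes, early patterning factors of neural and other tissue, with 4 of 5 tested members called against 0.0532 expected (adjusted p = 1.85e-05). IRX3 rose from 0.194 RPKM to 7.48 in KD1 and 4.67 in the library labelled KD2, IRX1 from 0.339 to 4.98 and 3.09, IRX2 from 3.27 to 20.6 and 15.9, and IRX5 from 0.129 to 2.62 and 1.90. Of the cadherin stem 3 of 12 were called higher, CDH2, CDH10 and CDH11 (adjusted p = 0.0551).

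The hESC knockdown libraries diverged in genes of several lists. TBXT, the primitive streak factor, stood at 0.053 RPKM in the control, 61.2 in KD1 and 4.10 in the library labelled KD2. FOXA2 stood at 0.301, 71.2 and 11.8, and SHH at 0.011, 13.9 and 1.09. The median of KD1 minus the library labelled KD2 was 0.80 log2 for the mesendoderm list (percentile 99.92 of matched random lists) and 0.34 for WNT targets (percentile 99.91). It was 0.79 for the epidermal list (percentile 99.94), of which KRT5, KRT14 and TP63 were too low to test. For BMP and TGF-beta targets it was 0.35 (percentile 99.92). It was -0.32 for neural crest (percentile 0.01), -0.13 for the neural progenitor list (percentile 1.9), -0.14 for the neuronal list (percentile 1.08), -0.18 for the SOX family (percentile 2.28), -0.45 for p53 targets (percentile 0) and -0.26 for the unfolded protein and integrated stress response (percentile 0.03). KD1 minus KD2 in hNPC was 0.25 log2 for the cell cycle (percentile 100), 0.27 for the unfolded protein and integrated stress response (percentile 99.95), -0.15 for the mesenchymal list (percentile 0.4), -0.16 for the SOX family (percentile 0.44) and -0.07 for the neural progenitor list (percentile 1.94). With 1 library of each siRNA set there is no replicate check, and no explanation was tested.

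A hypothesis was that part of the hESC response is present in hNPC below the threshold. For the genes called in hESC, with the 22 protocadherin gamma genes represented by 1 of them (197 genes), the median hNPC fold change signed by the hESC direction was 0.04 log2 (0.042), against -0.002 for the median of 10000 random sets and 0.019 at their 95th percentile (one-sided permutation p = 0.0007, which treats genes as independent). The random sets were matched on expression and on the difference between the hNPC knockdown libraries, since the calls favour genes where these lie close (median 0.119 log2 apart, against 0.15 for all genes). Both hNPC libraries lay on the side of the hESC change for 95 of the 197 genes (48.2%) and on the opposite side for 50 (25.4%), against 33.9% on either side in random sets. The median was 0.06 log2 in hNPC for the 123 genes higher in hESC and -0.01 for the 74 lower. These medians were not tested apart. The 197 genes include some that did not pass with the protocadherin gamma cluster entered as 1 gene. A shared response may exist, but it is small beside the hESC changes. Some genes, picked here as examples, lay on the same side of the control in both cell types and all 4 knockdown libraries. FRZB, APCDD1, LEF1, NKD1, APLNR and BTG2 lay above it, and SFRP2, USP44 and THY1 below it. On opposite sides in the cell types lay FST (4.20 log2 in hESC, -1.05 in hNPC), OLFM3 (3.94 and -0.49) and POLR3G (-2.61 and 0.61).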
